A study of Nematostella vectensis with 8 samples.

How the data were processed

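The 2 single-cell samples, adult polyps and planula larvae, were analysed. The 6 accessibility samples were not analysed here. Per the labels' protocols, polyadenylated RNA of lysed cells was reverse transcribed with primers that carry a cell barcode and a UMI, amplified by in vitro transcription, ligated to an adaptor with a batch barcode, and taken through 16 PCR cycles before sequencing on a NextSeq. Bowtie2 is named for these samples, per the submitters' processing notes. Versions, genome build and gene models are not given in the sources used here. The authors deposited UMI counts per gene and well for each stage, as whole numbers with no normalization. Intervals cover the counting of molecules and not amplification, dissociation or sorting.

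The deposited workbook ties 25728 wells to populations, amplification batches of 192 wells, cell barcodes and numbers of sorted cells. Of 134 amplification batches, 104 were used. The 16 batches (3072 wells) of ELAV-positive and SoxB2-positive cells, and 14 of the 22 batches listed for whole polyps in SB001, had no wells in the UMI tables. The populations were whole polyps, aboral ends and planulae of 3 ages, in 7 combinations of population and sequencing batch. Per the workbook, 1 sequencing batch had 6-base cell barcodes and 4-base UMIs, and the others had 7 and 8 bases. Its name there differs from every listed batch. SB000 was taken to be that batch, since it alone has 6-base barcodes, and its highest count of 1 gene in 1 cell was 243, under the 256 UMIs that 4 bases allow, against 2378 in SB001.

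There were 11888 adult wells with 24280 genes and 5281 larval wells with 20862 genes, with at least 98 and 99 UMIs per well, and 20354 genes were found in both stages. Wells under 100 UMIs (8 adult, 1 larval) and wells listed with no sorted cell (7 adult, 3 larval) were left out. There were 0 spike-in rows. Of 24788 identifiers, 0 matched the 38762 genes of the reference table of assembly jaNemVect1.1. The 25 lists of cell type markers and gene groups therefore had 0 matched members and gave no result, and the planned comparisons of named classes were replaced by comparisons of clusters by number.

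Lists, filters, scaling, clustering settings and the rule for printed identifiers were chosen before the data were examined. The comparisons of larval ages and of aboral ends, and the summary values (the median absolute log2 ratio, the shares in stage-restricted clusters and the composition distance), were chosen afterwards. UMIs were summed per stage or population and scaled to CPM, and ratios were taken for genes with at least 100 UMIs over both sums, with exact 95% conditional binomial intervals. A sum of 0 was set to 3 counts over the group. Printed identifiers had UMIs in at least 0.5 of the amplification batches of the higher group, an interval that excludes a ratio of 1 and the largest ratios, 2 per direction. Shares have exact Clopper-Pearson 95% intervals. Populations were set side by side after thinning to 823116 UMIs, over the 3000 genes with the highest mean share and with 1 count added, and whole-polyp batches within clusters over 500 genes.

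Cells were clustered with scanpy 1.11.5 (anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15): scaling to the median total, log1p, 2000 variable genes among those with a UMI in at least 10 cells, 30 principal components, 15 nearest neighbours and Leiden resolution 1 with seed 0. Ranges of composition distances came from 1000 resamplings of amplification batches with the clusters kept as they were. Per the deposited workbook, no well received more than 1 sorted cell. Scrublet called 0 of 11873 adult and 2 of 5277 larval cells. Whether doublets were rare or the caller missed them was not tested, and no cells were removed as doublets. Alternatives changed the minimum UMIs per cell and per gene, the scaling, the resolution, the number of variable genes, the seed, the doublets and the batches and populations included. Figures were drawn with matplotlib 3.10.9.

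The correlation of genes over cell barcodes was first computed on summed UMIs. The median Spearman's rho was then 0.31 for aboral ends and day 4 and 0.26 for day 2 and day 7. It was up to 0.27 for the other pairs, all from different sequencing batches and here called sequenced apart. Aboral ends and day 4, also listed in different batches, were kept out of these pairs. The correlation was then computed on shares of each barcode's UMIs, so that barcode depth does not enter. For the level of aboral genes at day 4, genes at least 50-fold above all other populations with at least 100 CPM (2 genes), and 20-fold with at least 50 CPM (4 genes), were tried first. These were too few, and genes low at day 2 and day 7 were used. For batch barcodes read 1 base out of frame, the bound against it was first the range of the shuffles, which reached 0.35 and so included the observed mean r of 0.34. It was changed after that result was seen to their 95th percentile, 0.27, and under the first bound the shift would have been ruled out. The label for crossing at first asked only for a higher rho than in pairs sequenced apart; it was brought to the written prediction, no correlation with populations sequenced apart, after the result was seen. The 9 aboral-rich clusters were first chosen with day 2 and day 7 in the rule too, and leaving these out gave the same clusters. For UMI saturation, the rule that a test which moves no distance by 1% decides nothing was added after its result was seen, and so was the test on genes with at most 12 UMIs per cell, whose own bound was set before its result.

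The steps were tested on simulated data. For the adult and larval comparison of 11442 genes, 200 of them changed 4-fold, 95.9% of true ratios lay inside their intervals, and 100% of raised and 100% of lowered genes came out at least 2-fold apart. Unchanged genes had a median absolute log2 ratio of 0.10. The intervals cover counting only, so the simulated coverage does not extend to spread between amplification batches. That spread was wide for v1g15302, at 2328 CPM ± 5036 (SD, n = 74) over adult amplification batches. For the clustering, 2400 simulated cells of 8 kinds gave 9 clusters with an adjusted Rand index of 0.93. This index does not show that the real clusters are stable. In the real data the share of larval cells in larva-restricted clusters went from 25.1% to 0% with another seed.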

Results

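Single cells of the starlet sea anemone Nematostella vectensis were profiled as adult polyps and as planulae, the swimming ciliated larvae. The method was MARS-seq, a plate assay in which each sorted cell receives a cell barcode and each transcript molecule a unique molecular identifier (UMI). Of the 8 samples of the series, the 2 single-cell samples, 1 adult and 1 larval, are described here. The 6 chromatin accessibility samples were not analysed here. Cell suspensions came from pools of 20 to 25 animals. The adult sample held 3 sequencing batches of whole polyps and 1 batch of aboral ends, the part of the animal opposite the mouth. The larval sample held planulae of 2, 4 and 7 days. With 1 sample per stage there was no test between stages, and exact intervals cover counting error only. No sequencing batch held both stages, so no stage difference was separated from sequencing batch.

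The adult stage kept 11873 cells with 9276742 UMIs, and the larval stage 5277 cells with 4194361 UMIs. The median was 542 UMIs and 308 genes per adult cell, and 437 UMIs and 275 genes per larval cell. Aboral ends were deepest, with a median of 906 UMIs over 3412 cells. Whole polyps had medians of 321 UMIs over 4357 cells (batch SB000), 439 UMIs over 1281 cells (SB001) and 605 UMIs over 2823 cells (SB003). Planulae had medians of 466 UMIs at day 2 (1325 cells), 396 UMIs at day 4 (2616 cells) and 539.5 UMIs at day 7 (1336 cells). The files do not pair gene identifiers with names, and 0 of 24788 identifiers matched the reference gene table. At most 2 identifiers are therefore printed per direction of a comparison, and cell clusters stay unnamed.

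The stage comparison asked which transcripts separate the adult polyp from the larva. In the adult, v1g15302 stood at 2146 CPM (19912 UMIs), against 1.19 CPM (5 UMIs) in the larva, a ratio of 1801 (exact 95% interval 771 to 5546). NVE1179 had 6583 adult UMIs (709.6 CPM) and 0 larval UMIs. It was at least 992-fold higher in the adult with the larva set to 3 counts, or 0.715 CPM, and the exact 95% interval of its ratio reached down to 807. Both belonged to whole polyps and not to aboral ends: v1g15302 reached 757, 4325 and 6235 CPM in batches SB000, SB001 and SB003 and 0.533 CPM in aboral ends. NVE1179 reached 358, 2164 and 1694 CPM in these batches, with 0 UMIs in aboral ends. Cluster 17 held 89.2% of the adult UMIs of v1g15302 and 81.9% of those of NVE1179, but only 266 of 11873 adult cells (2.24%). Both ratios thus rest largely on few cells, which the intervals do not cover. Over adult amplification batches NVE1179 stood at 787 CPM ± 1729 (SD, n = 74). When each cell weighed the same, the log2 ratio of v1g15302 was 9.06 in place of 10.81, with at least 400 UMIs per cell it was 11.42, and without 1 amplification batch of day-2 planulae it was 11.48.

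In the larva, v1g238806 stood at 97.5 CPM (409 UMIs), 90.5-fold above the adult (exact 95% interval 48.7 to 190.1), where it had 1.08 CPM (10 UMIs). It was mainly a day-7 transcript, with 307 CPM at day 7, 36.1 CPM at day 2 and 1.51 CPM at day 4. Cluster 10 held 82.6% of its larval UMIs, which came from 15 of the 30 larval amplification batches, the groups of 192 wells processed together. Only 1.63% of larval cells held a UMI of v1g238806. v1g202723 was 73.0-fold higher in the larva (37.9 to 161), at 70.8 CPM (297 UMIs) against 0.970 CPM (9 UMIs), and was found in 29 of 30 batches. It was highest at day 2, at 189 CPM, with 36.6 CPM at day 4 and 29.1 CPM at day 7. Without aboral ends and day-4 planulae its log2 ratio of adult over larva went from -6.19 to -8.13. That of v1g238806 went from -6.50 to -8.17 with at least 400 UMIs per cell, to -4.51 when each cell weighed the same and to -7.80 without 1 amplification batch of whole polyps.

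**Figure D1:**
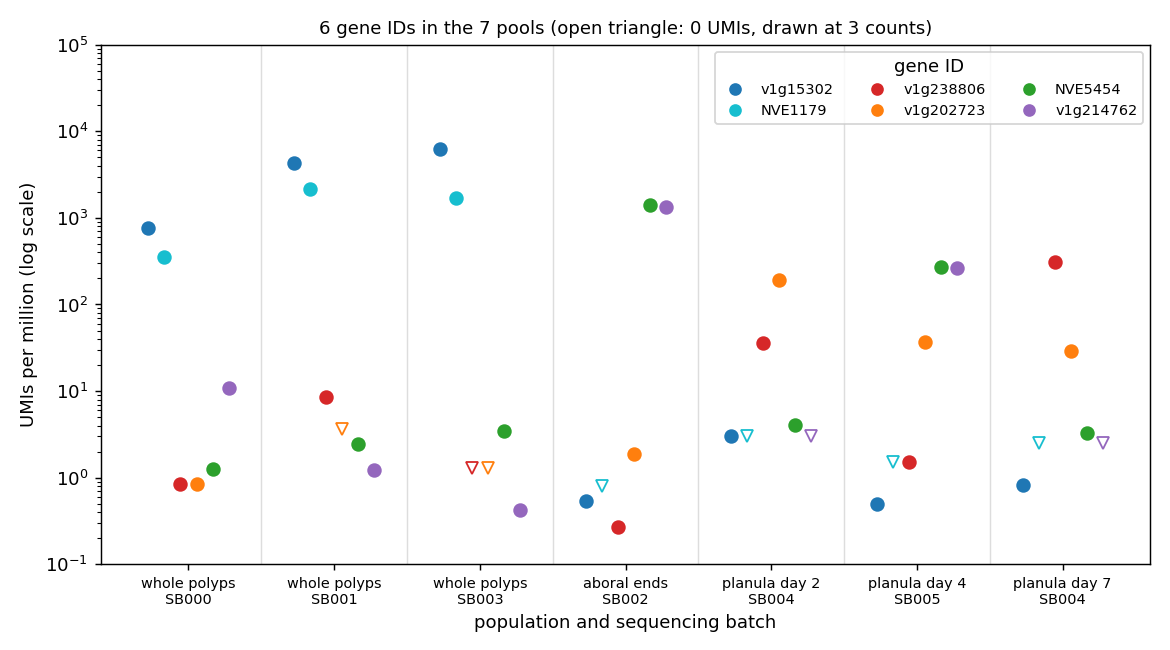
Depth-scaled UMIs (CPM, y axis, log scale) of 6 gene identifiers in the 7 combinations of population and sequencing batch (x axis), 1 filled point per sum over cells, with an open triangle at the level of 3 counts where 0 UMIs were found. v1g15302 and NVE1179 stand above all others in whole polyps only, v1g238806 is highest at day 7 and v1g202723 at day 2, and NVE5454 and v1g214762 are highest in aboral ends and next highest in day-4 planulae, at 268 and 261 CPM.

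Over the 11538 genes with at least 100 UMIs, the median absolute log2 ratio of adult over larva was 0.78 (rank-based 95% interval over genes 0.76 to 0.80), and it was 0.91 without aboral ends and day-4 planulae. To set this beside the spread between batches, every population was thinned to 823116 UMIs and compared over 3000 genes. The 12 pairs of an adult and a larval population differed by a median absolute log2 ratio of 0.74 to 1.27, and the 3 pairs of whole-polyp batches by 0.55 to 0.60. By this measure each stage difference exceeded each difference between whole-polyp batches. Every adult and larval pair also differed in sequencing batch, so the whole-polyp pairs do not separate stage from batch. The smallest stage difference, 0.74, was that of aboral ends and day 4, whose shared counts were not settled. By r across genes this pair (0.77) was closer than SB000 and SB001 (0.74) and SB001 and SB003 (0.73), but not than SB000 and SB003 (0.78). Aboral ends and whole polyps differed by 0.53 to 0.68, and the larval ages by 0.37 to 0.67.

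Among planulae, day 7 was compared with day 2, which shared a sequencing batch. Their transcripts were also shared by cell barcode (median Spearman's rho 0.21 over 127 abundant genes, at most 0.036 in 100 shuffles), and whether the few UMIs on the low sides belonged to those cells was not settled. v1g203954 was higher at day 7, at 227 CPM (273 UMIs) against 2.01 CPM (2 UMIs), a ratio of 113 (exact 95% interval 31.0 to 939). NVE18256 was 47.7-fold higher at day 7 (24.0 to 111), at 382 against 8.02 CPM, and 72.4% of its day-7 UMIs lay in cluster 25. The same cluster held 60.8% of the day-7 UMIs of v1g203954. Only 8 of 1336 day-7 cells lay in cluster 25, so both ratios rest largely on few cells, which the intervals do not cover. At day 2, NVE1718 was 16.3-fold higher (12.2 to 22.2), at 678 against 41.5 CPM, and v1g174671 was 16.3-fold higher (13.6 to 19.6), at 1773 against 109 CPM. Cluster 13 held 89.8% of the day-2 UMIs of v1g174671. NVE18256, NVE1718 and v1g174671 had UMIs in all 8 amplification batches of the age where each was higher, and v1g203954 in 5 of 8. Over 3228 genes the median absolute log2 ratio of day 7 over day 2 was 0.70 (0.67 to 0.73), and the median log2 ratio was -0.30. When each cell weighed the same, the log2 ratios of v1g203954, NVE18256, NVE1718 and v1g174671 went from 6.82, 5.57, -4.03 and -4.03 to 5.15, 4.56, -3.06 and -2.66. Without 1 amplification batch of day 7, those of v1g203954 and NVE18256 were 5.59 and 4.99, without another that of v1g174671 was -4.67, and without either of 2 batches of day 2 that of v1g203954 was 7.65 or 7.49.

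Aboral ends were compared with whole polyps. All aboral cells came from sequencing batch SB002 and all whole-polyp cells from SB000, SB001 and SB003, so body region was not separated from sequencing batch. NVE5454 was 593-fold higher in aboral ends (exact 95% interval 346 to 1114), at 1395 against 2.35 CPM, and v1g214762 was 266-fold higher (184 to 401), at 1349 against 5.07 CPM. Both had UMIs in 18 of 18 aboral amplification batches. Cluster 18 held 84.1% of the aboral UMIs of v1g214762, but only 45 of 3412 aboral cells (1.32%), against 1.96% of whole-polyp cells. NVE5454 was less concentrated, with 24.6% of its aboral UMIs in its main cluster, cluster 7. In the opposite direction, v1g15302 had 2 UMIs in aboral ends and 19910 in whole polyps, and was 6763-fold lower in aboral ends (1872 to 55849). v1g26281 had 0 UMIs in aboral ends and 11828 in whole polyps, at least 2679-fold lower with aboral ends set to 3 counts, while the exact 95% interval reached down to 2178-fold. It was found in 56 of 56 whole-polyp amplification batches. The whole animal includes its aboral end, yet NVE5454 stood at 1.27, 2.43 and 3.43 CPM in the 3 whole-polyp batches. Over 9580 genes the median absolute log2 ratio was 0.59 (0.58 to 0.61). The log2 ratio of v1g214762 (8.06) was 11.06 without SB000, 9.39 without 1 amplification batch of SB000, 10.47 and 10.64 with at least 200 and 400 UMIs per cell, and 5.67 when each cell weighed the same. That of v1g15302 (-12.72) was -13.39 without SB000 and -13.64 or -13.62 without either of 2 aboral amplification batches. With each cell weighed the same, those of v1g15302 and v1g26281 were -11.02 and -10.58.

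Transcripts abundant in aboral ends were also counted in the libraries of day-4 planulae, and whether they belonged to day-4 cells was not settled. NVE5454 stood at 268 CPM at day 4, but at 4.01 CPM at day 2 and 3.32 CPM at day 7. v1g214762 stood at 261 CPM at day 4, with 0 UMIs at day 2 and day 7, where 3 counts are 3.01 and 2.49 CPM. For the 95 genes with at least 50 CPM in aboral ends and at least 20-fold less at day 2 and day 7, the day-4 level was a median of 17.6% of the aboral level (interquartile range 15.4% to 24.2%). For 20 genes of day-4 planulae at least 20-fold lower in each whole-polyp batch, the aboral level was 8.93% of the day-4 level (7.28% to 11.4%). NVE17328 is an example chosen after its values were seen. Its UMIs were summed over wells with the same cell barcode, and the barcodes fell into 2 groups by their aboral UMIs. Between aboral ends and day 4, Spearman's rho was 0.52 over the 80 barcodes with under 100 aboral UMIs (Pearson's r 0.44) and 0.52 over the other 112 (r 0.53). Against day 7, rho was 0.17 (r 0.13) and -0.044 (r 0.11) in these groups. Barcode depth enters such sums; with NVE17328 as a share of each barcode's UMIs, rho in these groups was 0.32 and 0.54 for day 4 and ran from -0.10 to 0.25 for the other 4 populations and batches with 7-base cell barcodes. Barcodes are technical units, so no p-value is given.

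**Figure D2:**
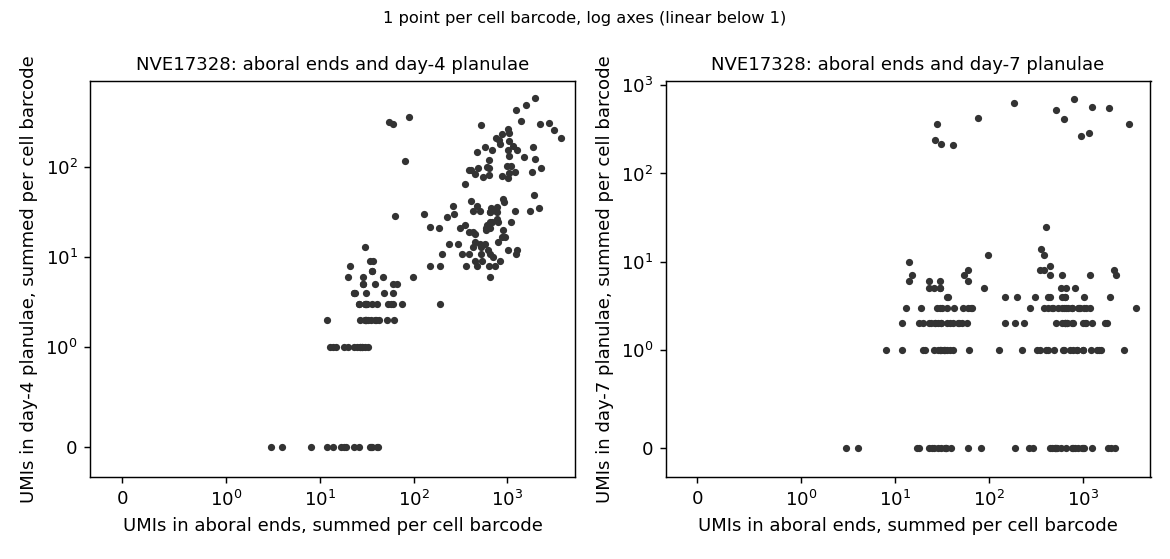
UMIs of NVE17328 summed over all wells with the same cell barcode, 1 point per barcode (192 barcodes), in aboral ends (x axes) against day-4 planulae (y axis, left) and day-7 planulae (y axis, right), on log axes that are linear below 1. The counts rise together for day 4, with a median of 2 day-4 UMIs for barcodes under 100 aboral UMIs and 33 for the others, and not for day 7, with a median of 2 in both groups.

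Joint clustering of the cells of both stages gave 27 clusters. Cluster 2 held 7.99%, 15.7% and 33.4% of whole-polyp cells in SB000, SB001 and SB003 (17.6% of all of them, exact 95% interval 16.8% to 18.5%, and 27.9% without SB000), 10.7% of aboral cells and 0 of 1325 day-2 cells, which allows a share of up to 0.278%. Cluster 17 held 1.74%, 1.87% and 5.88% of cells in these whole-polyp batches (3.14% of all, 2.78% to 3.54%) and 0 of 3412 aboral cells, which allows up to 0.108%. It was not confined to whole polyps, with 0.377%, 0.0382% and 1.05% of cells at days 2, 4 and 7. Cluster 6 held 4.48%, 10.9% and 5.42% of cells in these batches, 5.01% of aboral cells and 6.04%, 5.05% and 5.01% of cells at days 2, 4 and 7. Whole-polyp batches differed: cluster 1 took 40.005% of cells in SB000, the batch with 4-base UMIs, and 4.14% and 4.53% in SB001 and SB003. Per amplification batch, cluster 2 took 16.9% ± 13.5 (SD, n = 56) of whole-polyp cells.

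The largest shares of larval cells lay in clusters 4 (25.1%) and 3 (13.5%), and clusters 4, 10 and 11 were mostly larval, at 91.7%, 86.7% and 86.4% with both stages weighted equally. Cluster 4 held 18.5% of cells at day 2 (exact 95% interval 16.4% to 20.7%), 23.4% at day 4 and 35.3% at day 7 (32.7% to 37.9%), against 1.76% of whole-polyp cells. Per amplification batch its share was 18.5% ± 5.41 (SD, n = 8) at day 2 and 35.1% ± 5.19 (SD, n = 8) at day 7. Cluster 11 held 14.0% of day-2 and 7.41% of day-7 cells, and cluster 13 held 6.57% and 1.87%. The composition distance, the percentage of cells that would have to change cluster to turn one population into another, was 27.7% between day 2 and day 7 (21.8% to 35.6% over resampled amplification batches), and ran from 13.1% to 56.2% over the other settings tried. Whole-polyp batches SB001 and SB003 were 35.0% apart in the main setting, so the distance between these ages did not exceed that between 2 batches of whole polyps. Clusters at least 90% adult, with both stages weighted equally, held 26.0% of adult cells, and 1 cluster at least 90% larval held 25.1% of larval cells. These shares were not stable. With 1000 variable genes the adult share was 7.54%, and with another random seed alone or at Leiden resolution 0.5 the larval share was 0%. With genes at least 4-fold apart between the stages left out of the clustering the shares were 2.14% and 0%, but that filter itself favours a fall.

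Clusters 7, 8, 12, 15, 16, 20, 21, 22 and 23 each had a share of aboral cells more than 2 times that of every whole-polyp batch, and no larval share entered this choice. These 9 clusters held 58.0% of aboral cells (exact 95% interval 56.3% to 59.6%), and 5.39%, 14.0% and 12.04% of cells in whole-polyp batches SB000, SB001 and SB003. They held 4.08% of cells at day 2 and 9.43% at day 7, but 29.6% at day 4 (27.9% to 31.4%), where the library also held aboral transcripts such as NVE5454. The composition distance between aboral ends and whole polyps was 52.9% (48.5% to 57.5% over resampled amplification batches). Aboral ends came from a sequencing batch of their own, so body region was not separated from batch here. Batch by batch, aboral ends lay 49.7% from SB001 and 49.4% from SB003, which were 35.0% apart (32.6% to 39.2%). They lay 62.4% from SB000, which was itself 53.8% from SB001 and 52.5% from SB003.

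**Figure D3:**
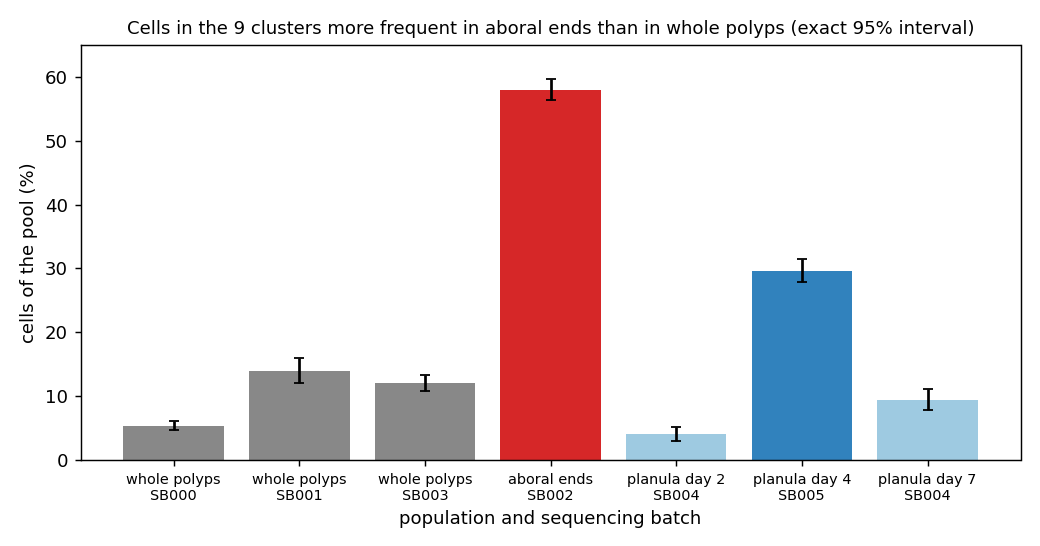
Percentage of cells (y axis) of each population and sequencing batch (x axis) in the 9 clusters whose share in aboral ends was more than 2 times that of every whole-polyp batch. Bars are shares with exact 95% binomial intervals, and day 4 (29.6%) stands above day 2 (4.08%) and day 7 (9.43%).

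Within clusters, adult and larval cells were compared where each stage had at least 50 cells. In these 16 clusters the median absolute log2 ratio of adult over larva lay between 0.46 (cluster 10) and 0.85 (cluster 1), with a median over clusters of 0.69. Larval sums ran from 28303 UMIs (cluster 23) to 991603 UMIs (cluster 4). Counting noise thus differed, and the range does not rank stage differences among the clusters. In some of them most adult cells were aboral and most larval cells were of day 4. In cluster 8 these were 517 of 641 and 198 of 211 cells, and in cluster 23 they were 107 of 113 and 56 of 64. Whether aboral transcripts at day 4 belonged to day-4 cells was not settled, so such ratios are not plain stage differences. Of the adult cells of cluster 1, 87.1% came from SB000, and without that batch its value was 0.63 and those of the 16 clusters lay between 0.51 (cluster 10) and 0.78 (cluster 16). In clusters 1, 3, 5 and 6 the same depth could be set for whole-polyp batches SB001 and SB003 and day-7 planulae. In cluster 3 the polyp batches differed by 0.59 and lay 0.67 and 0.75 from day 7. In cluster 5 they differed by 0.66 and lay 0.71 and 0.88 from day 7. In all 4 clusters both polyp batches lay farther from day 7 than from each other.

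Genes per cell were compared after each cell was thinned to 300 UMIs. Day-2 planulae had a median of 226 genes per cell (843 cells, 482 too shallow), day 4 had 208 (1616 cells, 1000 too shallow) and day 7 had 210 (885 cells, 451 too shallow). Aboral cells had 197 genes (3088 cells, 324 too shallow). Whole polyps had 228, 195 and 191 genes in SB000, SB001 and SB003, with 2061, 404 and 739 cells too shallow. Their spread was wider than that between larval ages only through SB000, the batch with 4-base UMIs. SB001 and SB003 alone spread less than the larval ages. Unthinned medians were 292, 250 and 319.5 genes at days 2, 4 and 7, 411 in aboral ends, and 230, 253 and 302 in the whole-polyp batches. Cells of cluster 17 had 158 genes at 300 UMIs and those of cluster 1 had 238. Of the 2233 cells of cluster 1, 1743 came from SB000, the batch with 4-base UMIs, and 1108 reached 300 UMIs. The contrast of these clusters was therefore not separated from that batch.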

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

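The test in this part was written before its result was seen. A signal was found in wells that the comparisons do not use: 10 of the 272 wells listed with no sorted cell in the amplification batches that have deposited wells (3.68%, exact 95% interval 1.78% to 6.66%) were among the deposited wells, with a median of 114 UMIs and a range of 104 to 258, against a median of 507 in kept cells. No deposited well had fewer than 98 UMIs, so these values are bounded from below and the other empty wells could not be assessed. There were 5 such wells in aboral ends, 2 in whole-polyp batch SB000, 2 at day 2 and 1 at day 4. For the test that follows, the batches of aboral ends and day 4 were taken as 1 sequencing set. None of the 4 wells that could be tested came from that set. A candidate explanation is counts crossing between wells with one cell barcode, for which the profile of a well should match other wells of its barcode better than 95% of other barcodes do: this held in 1 of 4 wells, with 100%, 89.5%, 82.5% and 81.7% of other barcodes below the own one. The bound set beforehand against crossing, at most 1 well, was thus met, but it was set for 10 wells, and the barcodes of 6 were carried by no sorted cell, so crossing stays open; no biological explanation was tested.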

How the results depend on the processing

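The alternatives without certain populations or batches, with empty wells kept and without genes apart between the stages, and all those for day 7 over day 2, for aboral ends over whole polyps and for single clusters without SB000, were chosen after seeing the data. No log2 ratio of an identifier chosen for 1 of the 3 comparisons changed direction under those run for it. The identifiers were chosen for the largest ratios in the same data, which nearly fixed this outcome, so it is no sign of stability. The median absolute log2 stage ratio (0.78) was 0.80 with at least 400 UMIs per cell, 0.71 with the mean of per-cell CPM, 0.81 with a gene minimum of 50 UMIs and 0.91 without aboral ends and day-4 planulae, and stayed in its interval under 5 other alternatives. With each of 104 amplification batches left out, it was 0.77 to 0.79. With the clusters kept as they were, so that a new clustering is not covered, the adult-restricted share was 25.6% to 26.4%, the larva-restricted share 24.6% to 25.7%, the day 2 to day 7 composition distance 26.2% to 30.04% and that of aboral ends and whole polyps 52.0% to 53.8%. The median absolute log2 ratio of day 7 over day 2 (0.70) was 0.75 with at least 400 UMIs per cell, 0.60 with median-of-ratios scaling, 0.58 with the mean of per-cell CPM and 0.69 to 0.73 with each of 16 amplification batches left out. That of aboral ends over whole polyps (0.59) was 0.63 with median-of-ratios scaling, 0.62 with the mean of per-cell CPM, 0.65 with a gene minimum of 50 UMIs and 0.59 to 0.61 with each of 74 batches left out. In the order adult-restricted share (26.0%), larva-restricted share (25.1%) and day 2 to day 7 distance (27.7%), values were 34.6%, 23.3% and 35.5% with at least 200 UMIs per cell, 21.6%, 26.4% and 41.6% with at least 400, 19.9%, 0% and 13.1% at Leiden resolution 0.5, 27.2%, 19.7% and 39.0% at resolution 2, 7.54%, 18.6% and 39.3% with 1000 variable genes and 27.5%, 12.6% and 24.4% with 4000. They were 25.2%, 0% and 31.6% with seed 1, 27.9%, 32.2% and 17.4% without the 2 doublet calls, 40.9%, 41.3% and 56.2% without aboral ends and day 4, 26.4%, 25.7% and 48.2% without SB000, and 2.14%, 0% and 18.4% without genes 4-fold apart between the stages. A new seed or 2 fewer cells moved the larva-restricted share, so it is not a stable quantity. The aboral to whole-polyp distance (52.9%) was 58.7% with 4000 variable genes, 47.7% without SB000 and 48.1% without genes apart between the stages, and stayed in its range under 7 others. The within-cluster median (0.69) was 0.82 with median-of-ratios scaling and moved by less than 1 SD over clusters under 4 others. The cause of these moves was not tested. Clustering each stage on its own gives no value on these scales, and alternatives for gene lists, held-out gene groups and ELAV genes were not run, since no identifier could be named. No paired analysis was possible because there was 1 sample per stage and the accessibility samples, which carry replicate numbers, were not analysed here. Depth limits rare transcripts: 3 counts are 0.323 CPM in the adult and 0.715 CPM in the larva.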

Other observations

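All tests in this part were chosen after the result was seen, except those of substituted bases and of UMI saturation. When each stage was clustered on its own there were 32 adult and 23 larval clusters. Of these, 16 pairs were each other's best match over 2000 genes, with a median r across genes of 0.40 (0.24 to 0.84). The pairs held 61.2% of adult and 76.99% of larval cells. How many such pairs unrelated clusters would give was not computed, so the pairs cannot be read as matched cell types.

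Aboral ends and day-4 planulae shared transcripts by cell barcode. Over 129 abundant genes the median Spearman's rho was 0.21, against at most 0.045 in 100 shuffles. It was 0.032 to 0.10 for the 13 other pairs of populations from different sequencing batches. Of these 13, 9 also exceeded all of their own shuffles, so the absence predicted for them was not met in full. Leaving the aboral and day-4 pair out of this set takes it as sequenced together, which the workbook does not state. A candidate explanation is counts crossing between libraries sequenced together, since days 2 and 7 of 1 sequencing batch also had 0.21 and aboral genes reached day 4 in a narrow range of ratios (upper over lower quartile 1.57); the workbook, however, lists SB002 and SB005 as separate batches, and crossing stays open. Day-4 cells of the 9 aboral-rich clusters met aboral cells of the same barcode and cluster 1.82 times as often as in shuffles (at most 1.11), which argues against shared cell types as the whole cause. Substituted bases in batch barcodes are argued against (median r 0.20 for 80 batch pairs differing at 2 bases, reached by 372 of 1000 shuffles). A barcode read 1 base out of frame stays open for a part of the sharing (mean r 0.34 for 11 pairs, reached by 3 of 1000 shuffles). The 241 batch pairs not related by such a shift still had a mean r of 0.21, which the shift does not account for. A true aboral-like cell population at day 4 beside crossed counts stays open too.

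Whole-polyp batch SB000, with 4-base UMIs, stood apart from SB001 and SB003 in cluster composition (53.8% and 52.5%, against 35.0% between them). Passing the counts of both through the same limit removed 5.59% and 5.95% of their UMIs and left 99.6% of their median absolute log2 distance to SB000 (0.62), which met the bound set beforehand against saturation, but no distance moved by 1%, so this test decided nothing. Clustered on the 23476 genes with at most 12 UMIs in any whole-polyp cell, SB000 lay 33.7% to 35.5% from SB001 and 28.6% to 32.1% from SB003 over 5 seeds, against 23.9% to 25.3% between SB001 and SB003. Over resampled amplification batches the lower end of the smaller distance was as low as 0.85 times the upper end of the latter, where a value above 1 would have argued against saturation as the whole source, so saturation stays open. Chemistry, depth and differences between animals stay open too and were not tested.

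Genes higher at day 7 than at day 2 tended to be higher in whole polyps than at day 4. Across 11538 genes, which are not independent replicates, r between these log2 ratios was 0.23, 0.27 and 0.24 for SB000, SB001 and SB003, 0.22 for aboral ends and -0.022 for the ratio of 2 whole-polyp batches. That last ratio holds no day-4 values, so its r is not a baseline for the others. As a hypothesis, a larval change towards the adult state would give the positive r values. A shift in the mix of cell types would give such values too and was not separated from it, and the day-4 values carry aboral transcripts.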
